A study of Mus musculus with 4 samples.

How the data were processed

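RNA from 2 tissues of the mouse embryo at 10.5 days post coitum (dpc) was compared on 4 two-colour oligonucleotide arrays. The tissues were metanephric mesenchyme (MM), the mesenchyme that forms the nephrons of the permanent kidney, and intermediate mesoderm (IM), the strip of mesoderm from which the urogenital system arises. Per the labels, the material was dissected primary tissue of both sexes, the RNA was amplified with an amino allyl kit, and each array carried both tissues directly with no common reference. Arrays 1 and 2 had MM as channel 1 and IM as channel 2, and arrays 3 and 4 had the channels exchanged. On arrays 3 and 4 the labels cross the nouns of the tissue names, and these were read as the same 2 tissues.

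The deposited values are log2 ratios, 1 per probe and array. Per the labels' protocols, spots were quantified with Imagene 5.5, and the signal and control channels of arrays 3 and 4 were reversed to account for the dye swap. A lowess curve using 20.0% of the data at each point was fitted by the authors to log ratio against log intensity and applied to the control value, and control values under 10 were set to 10. Background correction, spot flags and probe filters are not given in the sources used here. The log base was read from the values: 98.9% to 100% of the ratios under 1 fell on a grid of thousandths when raised from base 2 (tolerance 0.01 thousandths), against 2.12% to 2.71% from base e and 1.39% to 21.1% from base 10. The lowest value, shared by all arrays, was -6.64, the log2 of a ratio of 0.01, and was treated as a floor and not as a measured fold. The deposited table holds no intensities, so signal over background is unknown and the number of arrays limits the precision.

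Direction was taken as MM over IM. The labels make this likely and do not settle it: the titles put MM before IM, channel 1 of arrays 1 and 2 was MM, and arrays 3 and 4 were already reversed, but the dye of each channel is not stated. No sign was changed.

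The labels do not say whether the arrays share RNA extracts, so p-values measure only the spread between these 4 arrays, which may be technical. Of 22702 probes, 14184 had a value on every array and were tested. Log2 ratios were fitted per probe with limma 3.58.1 in R 4.3.3, with an intercept for tissue and a term for channel orientation. Moderated p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Arrays of the same orientation resembled each other closely, and the residual of this fit comes from those pairs alone, so calls from the fit without the orientation term are given beside it. Errors are SDs over the 4 arrays and hold the difference between orientations.

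On simulated arrays with the real orientation effects, 200 of 14184 probes were changed. With the orientation term, 53% of changes of 0.5 and 89% of changes of 2 on the log2 scale were recovered, with 10 false calls. Without it, 3% and 61% were recovered, with 0 false calls. The simulated noise was only the spread within each orientation. Differences between extracts or array pairs were absent, so few false calls were built in and do not vouch for the calls on the real arrays. In a simulation with 1 of 25 lists shifted by 1 on the log2 scale, the list test called that list and 0 of the others. Genes there had independent noise, so correlation between genes was not covered. The shift of 1 was also above the means of the 3 lists called on the real arrays (0.256 to 0.499). No probe outside the shifted list was changed. The simulation thus does not cover shifts of the reported size or arrays with many changed probes.

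Gene names came from the platform annotation and were updated through a RefSeq gene table of the assembly GRCm38.p6, used for names alone. Of all probes, 17252 had 1 gene symbol, 156 had several and 5294 had none; 16572 of the first kind matched the table and 4 symbols changed. Probes with several symbols were not named. Each probe was tested on its own, and different probes of a gene are mentioned where they disagree.

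Before the data were examined, 26 gene lists, the alternatives and the rule for named genes were fixed. The lists cover MM specification, nephric duct and epithelium, posterior and anterior Hox genes, stroma, gonadal ridge, germ cells, endothelium, erythroid cells, leukocytes, somite and muscle, neural cells, endoderm, limb bud, cell cycle, retinoic acid, Wnt and Notch, BMP, FGF and Hedgehog, extracellular matrix, cadherins and integrins, cholesterol and fatty acid synthesis, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, stress response, and 6 genes recalled, without a source used here, as chosen by the study on these arrays. Lists with at least 5 measured genes were tested with limma's camera (preset correlation 0.01) on gene averages, adjusted over 25 lists, with fry beside it. An estimated correlation was tried as an alternative. Camera then rests on the few residual degrees of freedom left by 4 arrays, so a list that fails there is not shown to be unshifted. The rule named the 12 largest rises and 12 largest falls past the threshold with 1 symbol and the same sign on every array, leaving out Riken clones and unnamed transcripts. It also named up to 4 members of smallest p per list, and 18 kidney genes always, 1 of which is not reported here.

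A repeat of the first part of that rule, among probes above the floor and past the threshold in both fits, was chosen after the values were seen. So were Robo2, Elovl6, Cldn6, Shh, Ttr, Cubn, Apoa1, Tcf15, Nr0b1, Hoxb9, Chrdl1, Hspa8, Gapdh, Emx2, Foxa1, Rpl11, Hba-a1, Apoc1, Dab2, F10 and Selenop. Alternatives changed the orientation term, centring, scaling, array weights, the number of values required, the variance model, the averaging of probes, extreme ratios, the threshold, the test and the arrays used. Others, added after the data were seen, left out probes at the floor, averaged each orientation, or used each orientation alone.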

Results

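The arrays compared metanephric mesenchyme (MM) with intermediate mesoderm (IM), both labelled 10.5 dpc, asking which genes differ between the 2 mouse tissues. The ratios thus compare tissues of the same age and do not follow a precursor into its product. There were 4 direct hybridisations, 2 per channel orientation. Arrays 1 and 2 held 21509 and 21599 values and arrays 3 and 4 held 15812 and 16242, out of 22702 probes. The floor of -6.64 was reached by 16 and 8 values on arrays 1 and 2 and by 1672 and 1805 on arrays 3 and 4. Positive log2 ratios mean higher in MM, the likely direction from the labels, and values are given as mean ± SD over 4 arrays.

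Single genes of the kidney mesenchyme and posterior Hox genes were among those higher in MM, and single genes of gonad, muscle and extracellular matrix among those higher in IM. Of 25 gene lists tested as wholes, camera called 3: cholesterol and fatty acid synthesis, nephric duct and epithelium, and cell cycle. With an estimated correlation it called 0 (smallest adjusted p = 0.549). That setting has so few residual degrees of freedom on 4 arrays that a pass was unlikely, so its 0 calls decide little. Six2, a transcription factor of nephron progenitors, was 7.99-fold higher in MM (log2 3.00 ± 0.63, n = 4, limma adjusted p = 0.0021). Gdnf, the growth factor that draws out the ureteric bud, was 3.78-fold higher (1.92 ± 0.13, adjusted p = 0.000762). Wt1, a transcription factor of kidney and gonad, was 2.97-fold higher in IM (-1.57 ± 0.02, adjusted p = 0.000303). Hoxd13, a posterior Hox gene, had the largest ratio of the named genes at 5.96 ± 1.14.

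Of 14184 tested probes, 8779 passed the threshold in limma, 3371 higher and 5408 lower in MM. Without the orientation term 3968 passed, 1932 higher and 2036 lower, and all 3968 also passed with it, that is in both fits, and had the same sign on 4 arrays. Among these, 611 were at least 2-fold higher and 133 at least 2-fold lower in MM. Of the 5408 lower calls, 855 rested on a value at the floor, as did 0 of the 3371 higher ones. Leaving out array 3 or array 4 lowered the 8779 calls to 5808 or 5848. With each orientation averaged to 1 value, 0 probes passed in limma and 1526 had an unadjusted p under 0.05. In the fit with the orientation term, calls were so common that every tested list held members called in each direction. Such members alone do not set a list apart.

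Ratios followed the channel orientation closely. Across the 13191 probes above the floor, which are not independent replicates, Pearson's r was 0.836 between arrays 1 and 2 and 0.912 between arrays 3 and 4. Between orientations it was 0.113 to 0.274. Including probes at the floor it was -0.349 to -0.26 between orientations. The orientation term passed the threshold for 6332 probes and was larger than the tissue effect for 42.3%. The sign was the same in both orientations for 61% of probes above the floor, where the shares of each sign alone would give 50%.

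**Figure D1:**
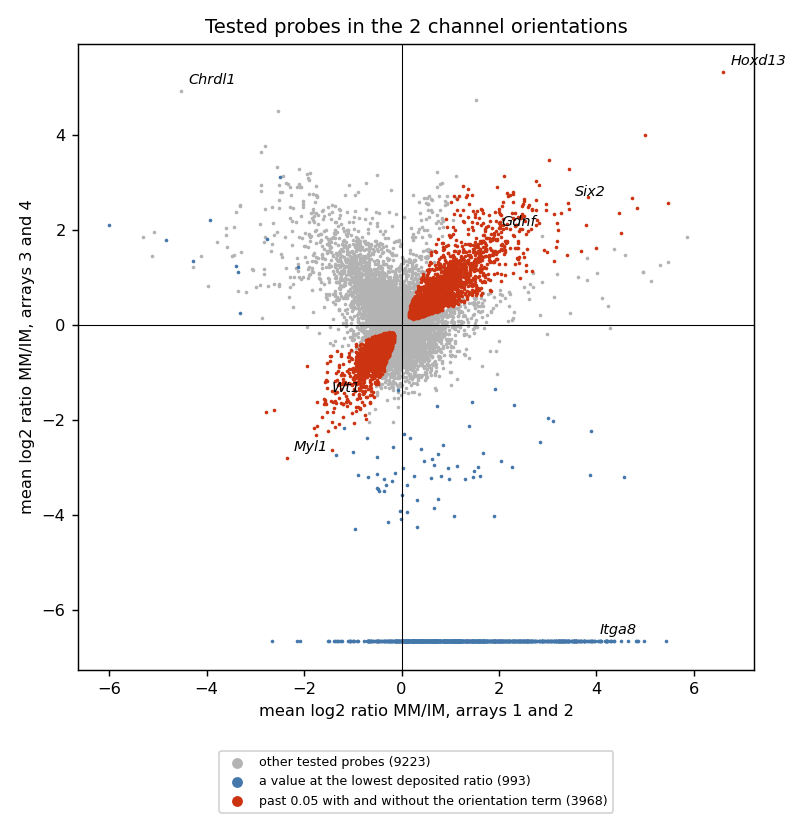
Each point is 1 of the 14184 tested probes, with its mean log2 ratio of MM over IM on arrays 1 and 2 (horizontal) and on arrays 3 and 4 (vertical). The 3968 probes past the threshold in both fits (red) lie in the quadrants of equal sign, and the 993 probes with a value at the floor (blue) lie mostly along -6.64.

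Among genes of MM specification, more were higher in MM than lower. Of 19 measured, 10 were higher, 4 were lower (7 and 2 in both fits) and 5 did not pass, with 14 past the threshold both over all probes and adjusted over the list alone. Besides Six2 and Gdnf, the higher genes were led by Sall4, a zinc finger factor (2.44 ± 0.55), Crym, a thyroid hormone binding protein (2.10 ± 0.24), and Hoxa11 (1.92 ± 0.59). Robo2, a Slit receptor that limits where Gdnf is expressed, was higher by 1.73 ± 0.55, and Osr1, an early marker of intermediate mesoderm, by 0.44 ± 0.17 (adjusted p = 0.00991). Pax2 (0.09 ± 0.17, adjusted p = 0.362), Hoxd11 (0.10 ± 0.37, adjusted p = 0.454) and Eya1 (0.35 ± 0.72, adjusted p = 0.28) did not pass. The list as a whole missed the threshold in camera (adjusted p = 0.0653, and 0.597 with an estimated correlation). It passed with probes at the floor left out (adjusted p = 0.035), with arrays scaled (adjusted p = 0.0459), without array 3 (adjusted p = 0.0386) and on arrays 1 and 2 alone (adjusted p = 0.037), but not on arrays 3 and 4 alone (adjusted p = 0.662). Itga8, the integrin subunit of this mesenchyme, read 3.67 and 4.16 on arrays 1 and 2 and stood at the floor on arrays 3 and 4, so its call as lower is not a measured fold.

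Several of the fixed kidney genes could not be tested. Ret had 1.04 and 0.42 on arrays 1 and 2 and no value on the others. Sall1 had 0.24 and -0.12 on arrays 1 and 2 and the floor on array 4. Cd24a had -0.29 and -0.02 on arrays 1 and 2 alone. Hoxc11 was not analysed here. Lhx1 was measured at 0.06 ± 0.68 (adjusted p = 0.851).

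**Figure D2:**
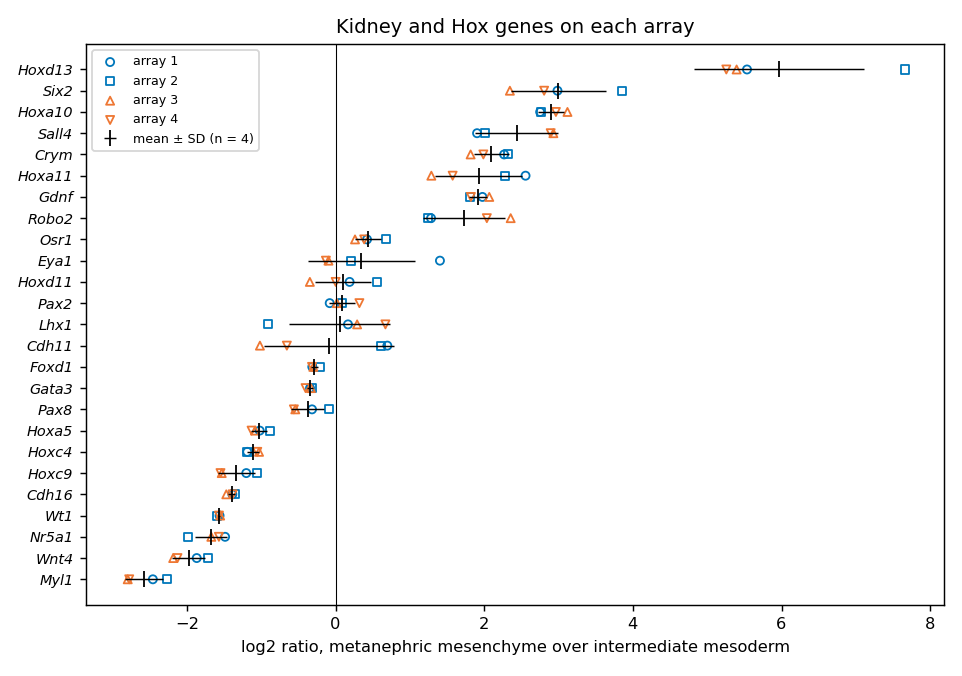
Log2 ratio of MM over IM (horizontal) for 25 kidney, Hox and mesoderm genes, with open symbols for each array and a bar for the mean ± SD of 4 arrays. Gdnf, Hoxa10 and Wt1 had nearly equal values on every array, while Cdh11 was positive on arrays 1 and 2 and negative on arrays 3 and 4.

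Posterior Hox genes (paralog groups 9 to 13), which pattern the hindmost body, were higher in MM for 8 of 11 measured with the orientation term and for 3 in both fits. The list had 2 lower (1 in both fits) and 1 that did not pass, with 10 past the threshold over all probes and 10 adjusted over the list alone. In both fits Hoxd13, Hoxa10 (2.90 ± 0.17) and Hoxa11 were higher. Hoxb9 averaged 3.03 but ranged from 0.88 to 5.55 between arrays and passed only with the orientation term. Hoxc9 was lower (-1.33 ± 0.24), and Hoxd9 read 2.38 and 1.95 on arrays 1 and 2 with the floor on the others. The list had an adjusted p = 0.0653 in camera and 0.549 with an estimated correlation; it passed without the orientation term (adjusted p = 0.0424), with probes at the floor left out (adjusted p = 0.035), without array 3 (adjusted p = 0.0386) and on arrays 1 and 2 alone (adjusted p = 0.0152), but not on arrays 3 and 4 alone (adjusted p = 0.347).

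Anterior Hox genes (paralog groups 1 to 8) had no common direction. Of 16 measured, 4 were higher, 4 were lower (2 and 3 in both fits) and 8 did not pass, and 8 passed adjusted over the list alone. Hoxc4 (-1.11 ± 0.08), Hoxa5 (-1.03 ± 0.11) and Hoxd4 (-0.53 ± 0.04) were higher in IM, and Hoxb4 (0.47 ± 0.10) was higher in MM. Their mean log2 ratio was -0.026, their median 0.045 and the camera direction up (adjusted p = 0.539).

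The nephric duct and epithelium list was shifted towards MM in camera. Of 20 measured genes, 12 were higher, 5 were lower (7 and 3 in both fits) and 3 did not pass, with 18 past the threshold adjusted over the list alone. Camera gave an adjusted p = 0.0487, and 0.549 with an estimated correlation. The higher members were led by epithelial adhesion and junction genes, Epcam (1.87 ± 0.06), Cldn6 (2.10 ± 0.77) and Cldn7 (1.36 ± 0.36), with the protease inhibitor Spint2 at 0.70 ± 0.11. Regulators and markers of the nephric duct itself went both ways. Cdh16, kidney cadherin (-1.40 ± 0.05), Gata3 (-0.35 ± 0.04) and Pax8 (-0.38 ± 0.22) were lower, the last only with the orientation term. Emx2 was higher (0.69 ± 0.36), and Pax2 and Lhx1 did not pass. Cdh1, the epithelial cadherin, read -0.35 and -0.07 on arrays 1 and 2 and 2.76 and 2.94 on arrays 3 and 4. The list lost its call without the orientation term (adjusted p = 0.094) and when arrays were centred on their medians (adjusted p = 0.0622). It also lost it without array 1 (adjusted p = 0.0729) or without array 2 (adjusted p = 0.0613), and within each orientation alone (adjusted p = 0.147 and 0.282). With array weights it was 0.0525 and with 3 or more values 0.0576.

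Of 18 measured genes of liver bud and gut endoderm, 9 were higher in MM, and 9 in both fits, but camera did not call the list. In the list 3 were lower (1 in both fits), 1 had probes of both directions and 5 did not pass, with 14 past the threshold adjusted over the list alone. Afp, a fetal serum protein, was 3.62-fold higher (1.86 ± 0.32), and the serum proteins Ttr (1.17 ± 0.38), Rbp4 (1.10 ± 0.11) and Apoa1 (1.02 ± 0.20) were higher too. So were the endocytic receptor Cubn (1.18 ± 0.10), the endodermal factor Hhex (1.11 ± 0.25) and Shh, the hedgehog ligand of gut epithelium (2.81 ± 1.44). Of 3 probes for transferrin, Trf, 2 gave 1.54 ± 0.21 and 1.55 ± 0.05, and the other was at the floor on arrays 3 and 4. The list had a camera adjusted p = 0.0653 (0.549 with an estimated correlation), 0.035 with probes at the floor left out and 0.0485 without array 3, but 0.237 without array 1. Its mean was 0.799 on arrays 1 and 2 alone (adjusted p = 0.0605) and 0.101 on arrays 3 and 4 alone (adjusted p = 0.459).

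Cholesterol and fatty acid synthesis gave the smallest list p-value. Of 21 measured genes, 14 were higher in MM, 4 were lower (10 and 3 in both fits) and 3 did not pass, with 18 past the threshold adjusted over the list alone. The sterol enzymes Cyp51 (2.18 ± 0.24), Nsdhl (1.44 ± 0.03) and Idi1 (1.19 ± 0.09) and the fatty acid enzymes Elovl6 (1.69 ± 0.24) and Fads1 (1.10 ± 0.31) were at least 2-fold higher. Camera gave an adjusted p = 0.0164, and 0.549 with an estimated correlation. With the preset correlation, camera also called the list without the orientation term (adjusted p = 0.00609) and without each array in turn (adjusted p = 0.0119 to 0.0443). It was the only list called with arrays centred, with array weights or with 3 or more values (camera adjusted p = 0.0132 to 0.0225). On arrays 1 and 2 alone its mean was 0.474 (camera adjusted p = 0.0588). On arrays 3 and 4 alone the mean was 0.525 (camera adjusted p = 0.0926), so the list passed in neither orientation alone.

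The cell cycle list was shifted towards MM in camera. Of 38 measured, 17 were higher, 10 were lower (10 and 2 in both fits) and 11 did not pass, with 27 past the threshold adjusted over the list alone. Mcm7 of the replicative helicase was 5.81-fold higher (2.54 ± 0.08), and Cdc45 (2.29 ± 0.35), the ribonucleotide reductase subunit Rrm2 (1.24 ± 0.21) and Hmgb2 (0.95 ± 0.30) followed. Camera gave an adjusted p = 0.0487 (0.597 with an estimated correlation). The call was lost with arrays centred (adjusted p = 0.0558), without array 1 (adjusted p = 0.0729) and without array 2 (adjusted p = 0.0956). It was also lost with array weights (adjusted p = 0.0525) and with 3 or more values (adjusted p = 0.0704). The mean log2 ratio was 0.49 within arrays 1 and 2 alone (adjusted p = 0.00622) and 0.023 within arrays 3 and 4 alone (adjusted p = 0.459).

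Several genes of gonad and adrenal cells were higher in IM, though camera did not call the gonadal ridge list. Nr5a1, the nuclear receptor that specifies gonad and adrenal cortex, was 3.20-fold higher in IM (-1.68 ± 0.22), with its partner Nr0b1 (-1.31 ± 0.26) and the adrenocorticotropin receptor Mc2r (-1.68 ± 0.17). Tcf21 (-0.65 ± 0.22) and Dlk1 (-0.62 ± 0.12) were also higher in IM, and Krt7 (0.50 ± 0.13) was higher in MM. Of 11 measured genes of the list, 3 were higher, 7 were lower (2 and 5 in both fits) and 1 did not pass, and 10 passed adjusted over the list alone. Its camera adjusted p was 0.539.

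Of 15 measured muscle and somite genes, 2 were higher in MM, 10 were lower (1 and 7 in both fits), 1 of the 10 at the floor, and 3 did not pass, with 14 past the threshold adjusted over the list alone. The light chain Myl1 was 5.95-fold higher in IM (-2.57 ± 0.26), as were the troponins Tnnt1 (-2.03 ± 0.36), Tnnt2 (-1.44 ± 0.48) and Tnni1 (-1.34 ± 0.33) and the somite factor Tcf15 (-0.95 ± 0.21). Des, the muscle intermediate filament, was the opposite (0.97 ± 0.13). Camera gave an adjusted p = 0.0653 (0.549 with an estimated correlation), 0.0424 without the orientation term, 0.035 with probes at the floor left out and 0.0386 without array 3, but 0.0956 without array 2. The list's mean was -0.57 on arrays 1 and 2 alone (adjusted p = 0.113) and -1.2 on arrays 3 and 4 alone (adjusted p = 0.0978).

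Neural genes were lower in MM for 15 of 20 measured, 3 of them at the floor, and higher for 4, with 1 not past the threshold and 19 past it adjusted over the list alone. In both fits 8 were lower and 2 higher, and the list's mean was 0.148 on arrays 1 and 2 alone and -1.37 on arrays 3 and 4 alone. Sox2, a factor of neural progenitors (-0.93 ± 0.04), the neuronal RNA-binding protein Elavl4 (-0.97 ± 0.40) and the neuronal tubulin Tubb3 (-0.49 ± 0.09) were higher in IM. The probes of Pax6 disagreed, at 1.58 ± 0.78 and -0.15. Camera did not call the list (adjusted p = 0.0656, and 0.549 with an estimated correlation). In camera it passed without array 3 (adjusted p = 0.0485), but not on arrays 1 and 2 alone (adjusted p = 0.456) or arrays 3 and 4 alone (adjusted p = 0.105).

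Of 29 extracellular matrix genes, 7 were higher in MM, 18 were lower (2 and 12 in both fits) and 4 did not pass, and 25 passed adjusted over the list alone. Bgn (-1.21 ± 0.26), Sparc (-1.14 ± 0.14), Col5a2 (-0.87 ± 0.07) and Timp1 (-0.76 ± 0.26) were lower members of smallest p. The list was not called (camera adjusted p = 0.172), and its mean was 0.025 on arrays 1 and 2 alone and -0.647 on arrays 3 and 4 alone. Of 19 stroma genes, 5 were higher, 7 were lower (4 and 7 in both fits) and 7 did not pass, and 12 passed adjusted over the list alone (camera adjusted p = 0.857). Col1a1 (-1.02 ± 0.11), Tbx18 (-0.86 ± 0.17, and -0.28 by another probe) and Tgfbi (-0.67 ± 0.11) were lower in MM, and Foxd1, the marker of kidney stroma, slightly so (-0.28 ± 0.05). Of 19 cadherins and integrins, 4 were higher, 10 were lower (2 and 2 in both fits), 6 of the 10 with a value at the floor, and 5 did not pass, with 15 past adjusted over the list alone (camera adjusted p = 0.545, mean -0.713, and -0.06 with probes at the floor left out).

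**Figure D3:**
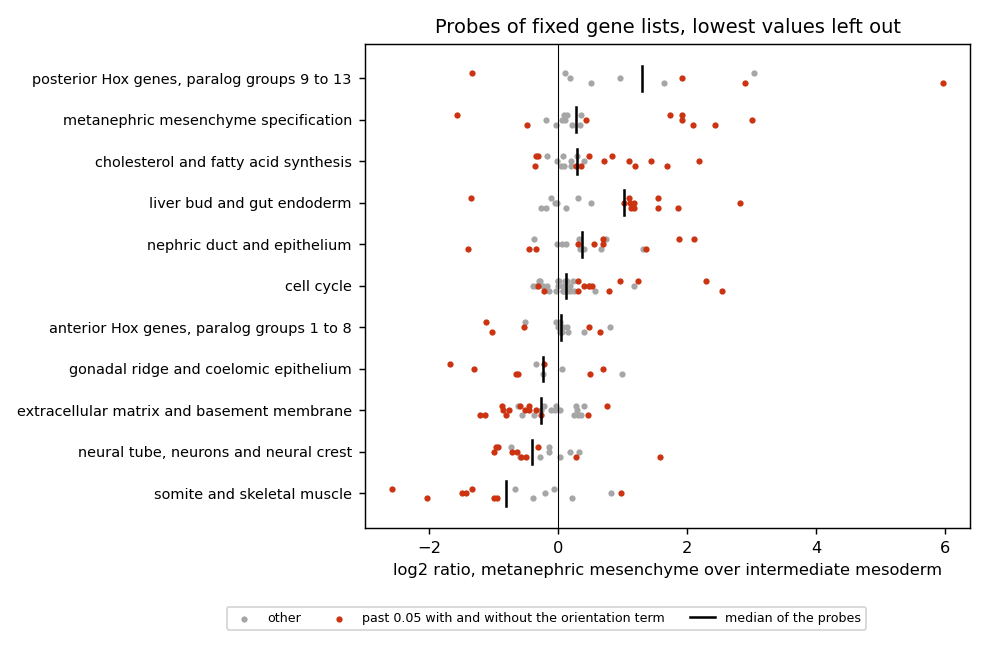
Log2 ratio of MM over IM (horizontal) for each probe of 11 fixed gene lists, leaving out probes at the floor, with the median of the probes as a bar. Probes past the threshold in both fits are red; those of posterior Hox genes reach 5.96 and those of muscle genes reach -2.57.

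Signalling genes changed in both directions. Of 27 Wnt and Notch genes, 9 were higher, 8 were lower (7 and 7 in both fits) and 10 did not pass, and 17 passed adjusted over the list alone. Wnt4, the signal that turns mesenchyme into nephron epithelium and acts in the gonad, was 3.93-fold higher in IM (-1.97 ± 0.22). The Wnt antagonist Sfrp1 was lower in MM by 2 probes (-1.52 ± 0.09 and -1.36 ± 0.22), the antagonist Frzb was higher (1.89 ± 0.55) and the Notch ligand Dll1 was lower (-0.91 ± 0.15). The mean of this list was -0.154, its median 0.037 and its camera direction up (adjusted p = 0.557). Of 28 BMP, FGF and Hedgehog genes, 12 were higher, 5 were lower (6 and 3 in both fits) and 11 did not pass, with 17 past adjusted over the list alone (camera adjusted p = 0.305). The FGF-responsive phosphatase Dusp6 (1.82 ± 0.30), the Hedgehog receptor Ptch1 (1.20 ± 0.05) and the BMP receptor Bmpr1a (0.98 ± 0.02) were higher in MM, and Bmpr2 was lower (-0.86 ± 0.25).

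Camera did not call any of the lists of other cells that the dissections could hold. A list that misses the threshold is not shown to be unshifted. Of 23 endothelial genes, 7 were higher, 10 were lower (6 and 4 in both fits) and 6 did not pass, with 17 past adjusted over the list alone (adjusted p = 0.934). Cd34 (0.79 ± 0.07) and Sox17 (0.75 ± 0.07) were higher in MM, and Tek (-0.52 ± 0.07) was lower. Of 17 erythroid genes, 4 were higher, 8 were lower (1 and 5 in both fits) and 5 did not pass, with 12 past adjusted over the list alone (adjusted p = 0.539), among them the embryonic globin Hbb-bh1 (-0.85 ± 0.13) and the erythroid membrane protein Ermap (-0.76 ± 0.09). Leukocyte genes were lower for 6 of 9 and higher for 1 (3 and 0 in both fits), with 7 past adjusted over the list alone (adjusted p = 0.172), as with Laptm5 (-0.53 ± 0.02) and Mrc1 (-0.54 ± 0.05). The mean of the leukocyte list was -0.148 on arrays 1 and 2 alone and -0.988 on arrays 3 and 4 alone. Germ cell genes were lower for 4 of 7 and higher for 2 (3 and 1 in both fits), with 7 past adjusted over the list alone (adjusted p = 0.569), with Alpl (1.85 ± 0.89) the highest and Ifitm3 (-1.06 ± 0.09) and Ifitm1 (-1.03 ± 0.10) the lowest. Of 10 limb bud genes, 4 were higher, 3 were lower (4 and 2 in both fits) and 3 did not pass, with 7 past adjusted over the list alone (adjusted p = 0.539), with Pitx1 (0.36 ± 0.07) and Alx4 (0.34 ± 0.11) higher and Meis2 (-0.52 ± 0.09) lower.

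Outside the lists, the largest rises named by the rule after Hoxd13 were Ogfr, the opioid growth factor receptor (4.50 ± 0.59), the hyaluronan-binding protein Tnfaip6 (4.02 ± 1.72), Ppfibp1 (3.85), Ttc30a1 (3.71 ± 1.41) and Txnip, a thioredoxin inhibitor (3.42 ± 1.28). Gpat4, Lpar6 (3.37 ± 0.16), Fjx1, Gfm1 (3.26 ± 0.26), Dnajc8 and N4bp3 completed the 12. Of these, Ppfibp1, Gpat4, Fjx1 and N4bp3 did not pass without the orientation term (adjusted p = 0.0601 to 0.1). The 12 largest falls were Ids, Hba-ps3, Ptprv, Adam7, Hspb7, Il1f5, Ptpn22, Zdhhc11, Gh, Olfr146, Adm and Clec4e. All 12 stood at the floor on arrays 3 and 4, so no fold is given. On arrays 1 and 2 their means were -2.65 for Ids to -0.70 for Clec4e.

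Among probes above the floor and past the threshold in both fits, the largest falls after Myl1 were Cdh10, Nfia (-2.20 ± 0.51), Igfbp7 (-2.03 ± 0.69) and Tnnt1. The probes of Cdh10, a neural cadherin, disagreed, with 1 at -2.31 ± 0.68, another not past the threshold at -0.21 ± 1.95 and another at the floor on arrays 3 and 4, as was another probe of Nfia. Wnt4, Klhdc4 (-1.92 ± 0.21), the glutathione transferase Gsta3 (-1.77 ± 0.20), the elastin crosslinking enzyme Loxl1 (-1.75 ± 0.49), Anp32a (-1.73 ± 0.36), Nr5a1 and Mc2r followed. The corresponding rises added Six2, Cul3 (2.95), Tdrd3 (2.94) and Hoxa10.

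Of 6 genes recalled, without a source used here, as chosen by the study on these arrays, 4 had a tested probe. Ywhaq (1.32 ± 0.44) and Scd2 (0.40 ± 0.24, adjusted p = 0.0499) were higher in MM, and Scd2 did not pass without the orientation term. Ewsr1 (0.69 ± 0.47, adjusted p = 0.0643) did not pass. Cdh11, an adhesion gene of mesenchyme, read 0.70 and 0.61 on arrays 1 and 2 and -1.02 and -0.66 on arrays 3 and 4 (adjusted p = 0.369). The list passed for 2 genes over all probes and 1 adjusted over the list alone. It is not taken as independent evidence, since by that recollection it was picked from these arrays. Rara had 6 probes, 0 of them with a value on every array.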

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

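Each of 175 probes of named genes and 3 measures per array was examined for 1 array standing far from the others. Chance alone would give about 8.9 such cases among 178, and 3 were found, each with array 2 apart. For Hoxd13, array 2 read 7.67 and the others 5.26 to 5.54, a gap of 0.884 of the whole range. For Col1a1, array 2 read -0.86 and the others -1.09 to -1.06, a gap of 0.906 of the range. For Foxd1, array 2 read -0.21 and the others -0.32 to -0.30, a gap of 0.839 of the range. The sign was the same on every array for all 3 genes.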

How the results depend on the processing

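The alternatives that averaged orientations, left out probes at the floor or used 1 orientation were chosen after the data were seen. The filter on dim probes was not run, as the table used here holds no intensity, so signal over background limits every ratio by an unknown amount. Counts of 8779 probes past the threshold, 3371 higher and 5408 lower, stayed within 1.5 times under centring, scaling, array weights, 3 or more values, robust variances, gene averages, winsorised ratios and the threshold of 0.10 (7157 to 9921 in all). They also did with probes at the floor left out (8130, 3448 and 4682). On arrays 3 and 4 alone they did too (7701, 3341 and 4360), but 1 orientation alone cannot separate dye from tissue effects. The next settings moved the counts. They became 3968, 1932 and 2036 without the orientation term. The difference between orientations then enters the residual, whose prior SD in limma was 0.158, against 0.0794 with the term. Apart from this, causes were not tested. An unmoderated one-sample test gave 3559, 1683 and 1876, and the 2-fold rule 931, 724 and 207. Leaving out probes at the floor together with the orientation term gave 4375, 2100 and 2275. Each orientation averaged gave 0, 0 and 0 (limma, smallest adjusted p = 0.461). Arrays 1 and 2 alone gave 5614 in all and 2905 lower. Arrays left out in turn moved some counts and not others, with 5808 to 6782 in all, 2480 to 2705 higher and 3295 to 4181 lower, and 981 to 2693 probes with an orientation effect against 6332; the total without array 1 (6703) or 2 (6782) and every higher count stayed within 1.5 times.

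Of 25 lists, 3 passed. The number was 1 with arrays centred, with array weights or with 3 or more values, 1 to 8 leaving out each array, 7 with probes at the floor left out, 5 with the orientation term left out as well, and 0 on arrays 3 and 4 alone. With an estimated correlation 0 passed in camera, 0 had an unadjusted p under 0.05 and the smallest adjusted p was 0.549. The few residual degrees of freedom of that setting make a pass unlikely, so it does not decide whether the lists shift. With fry, which asks whether genes move and not whether a list stands apart, 22 passed. Fry turned 3 directions to down: those of anterior Hox genes (mean -0.026) and ribosomal proteins (mean -0.016), which passed, and that of glycolysis and hypoxia, which did not (fry adjusted p = 0.207). Ribosomal proteins were also turned on arrays 1 and 2 alone, with a mean of -0.285 and an adjusted p of 0.00016, and without the orientation term their direction was down but not past the threshold (adjusted p = 0.442).

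Of 175 probes of named genes, 163 passed. Chrdl1 alone turned its direction, from 0.20 to -0.14 with scaled arrays and -0.51 with winsorised ratios; it read -4.45 and -4.62 on arrays 1 and 2 and 4.96 and 4.90 on arrays 3 and 4. Without the orientation term 40 lost their call, and 19 lost it when some array was left out.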

Other observations

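Stress and metabolic genes held further differences. Of 31 immediate early and stress genes, 12 were higher in MM, 10 were lower (10 and 5 in both fits) and 9 did not pass, with 22 past adjusted over the list alone. The chaperones Hspa8 (2.27 ± 0.18) and Hspa5 (1.60 ± 0.29 and 0.44 ± 0.21 by 2 probes), the antiproliferative gene Btg1 (1.04 ± 0.01), Myc (0.84 ± 0.05) and the asparagine synthetase Asns (0.68 ± 0.09) were higher. The list's mean was 0.198, its median -0.064 and its camera direction up (adjusted p = 0.539). Of 48 oxidative phosphorylation genes, 8 were higher, 23 were lower (2 and 11 in both fits) and 17 did not pass, with 33 past adjusted over the list alone (camera adjusted p = 0.172), as with Uqcrb (-1.16 ± 0.43), Cox6b1 (-0.64 ± 0.04) and Ndufa5 (-0.60 ± 0.18), while Uqcrc1 was higher (0.43 ± 0.04).

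Of 14 retinoic acid genes, 6 were higher, 5 were lower (4 and 1 in both fits) and 3 did not pass, with 11 past adjusted over the list alone (camera adjusted p = 0.497). The retinol dehydrogenase Rdh10 was 3.61-fold higher in MM (1.85 ± 0.18), and the retinaldehyde dehydrogenase Aldh1a1 was lower (-0.92 ± 0.08). Of 19 glycolysis and hypoxia genes, 7 were higher, 7 were lower (7 and 2 in both fits), 5 of the lower ones at the floor, 1, Gapdh, had probes of both directions and 4 did not pass, with 14 past adjusted over the list alone. Their mean was -0.66, their median 0.001 and the camera direction up (adjusted p = 0.726); with probes at the floor left out the mean was 0.269 and the median 0.228 (adjusted p = 0.0979). Pgk1 (0.89 ± 0.18) and Hk2 (0.81 ± 0.15) were higher in MM. The 20 tested Gapdh probes ranged from -1.52, with 1 array at the floor, to 1.98, with 6 past the threshold higher and 2 lower.

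Tests in the next paragraphs were chosen after the results were seen, with these exceptions. The list counts and camera result of ribosomal proteins were fixed before the data were examined. The prediction for further yolk sac genes was written before their values were read. The fit without the orientation term was repeated with the signs of the arrays changed. The real signs gave 3968 probes, 1 of the 8 sign patterns gave as many, and the highest of the others was 1, for the pattern that follows the channel orientation. With 8 patterns no share under 0.05 can be reached.

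Lower calls at the floor formed the first pattern. Of 855 such probes, 753 were positive on arrays 1 and 2, and 11.9% had a mean below 0 there, against 59.8% of the tested probes above the floor. The median on arrays 1 and 2 was 1.07, with quartiles of 0.38 and 2.12, so these arrays do not show higher expression in IM for these probes as a set. Arrays 1 and 2 share their channel orientation, so a dye effect cannot be told from a tissue difference there. A ratio set by the processing of dim spots on arrays 3 and 4 is consistent with these values. Whether such probes are higher in MM or in IM stays open, since arrays 3 and 4 hold no measured ratio for them.

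Epithelial and endodermal genes formed a second pattern: 22 genes of the lists were higher in MM above the floor, with a median of 1.10. More nephric duct in the MM sample did not show as a rise of 6 measured duct regulators and markers. Their median was -0.15 (SD 0.70), with 1 higher and 3 lower, and 5 kept their sign between orientations. The 22 genes were picked as higher, and 1 list holds most of these markers, so a gap between the medians was partly built in. It does not settle whether more nephric duct was the whole cause. For yolk sac visceral endoderm, the rise predicted for further genes of that tissue did not appear. This does not settle whether that tissue was a source, since the comparison was again with genes picked as higher. The 10 further genes, outside the lists, had a median of 0.02 (SD 0.74), and only 5 kept their sign between orientations. In the fit with the orientation term 3 of the 10 were higher and 3 were lower. Of these genes, Dab2 (-1.31 ± 0.54) and Apoc1 (-0.58 ± 0.11) were lower and Selenop (0.74 ± 0.24) higher in both fits. F10 (1.48 ± 1.11) was higher only with the orientation term. Gut endoderm stays open: 4 regulators had a median of 0 (SD 0.07), but with probes of a gene averaged 0 of them kept their sign between orientations, and the 2 Foxa1 probes disagreed (0.31 ± 1.93, and -0.27 ± 0.25 with 1 sign on every array). Expression of these genes by MM itself, the tissue difference the design names, may also account for the pattern and was not tested.

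Ribosomal protein genes were opposite by orientation. Of 67 measured, 26 were higher, 24 were lower (3 and 10 in both fits) and 17 did not pass, with 52 past adjusted over the list alone; their mean was -0.016, their median 0.055 and the camera direction up (adjusted p = 0.539). Above the floor, their sign differed between orientations for 62.1% of 66 genes, against 35.9% of all genes, with medians of -0.25 on arrays 1 and 2 and 0.26 on arrays 3 and 4. Rpl11 read -0.41 and -0.39, then 1.09 and 1.06, and Hba-a1 did likewise at -0.40, -0.37, 0.98 and 0.88. An effect of dye or spot brightness is consistent with this; a tissue difference beneath it cannot be told apart, since the quartiles on arrays 3 and 4 lay at -0.21 and 0.75.

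On arrays 1 and 2 alone, 4250 further probes had values, with 880 at least 2-fold higher on both and 259 at least 2-fold lower on both. They entered no test.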
